A study of Mus musculus with 8 samples.

How the data were processed

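RNA of the uterus was measured by sequencing in 8 libraries, 2 for each of proestrus, estrus, metestrus and diestrus, from female ICR mice staged by vaginal smear. Per the labels, polyadenylated RNA went into stranded libraries. The deposited values are counts per gene, made by the authors from aligned reads and not normalised. This unit was checked on the values, which are whole numbers with a different total in each library, from 17863546 to 21896786. The submitters' processing notes name STAR for alignment, featureCounts of the Subread package for counting and the mouse build GRCm38 (mm10). Versions, parameters, annotation release and strand setting are not given in the sources used here.

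The table holds 52308 genes. Symbols, biotypes and coordinates came from GENCODE M21, in which 52058 of the identifiers were found. The other 250 held at most 0.0107% of the counts of a library. Fam3d carries the older symbol Oit1 in that annotation. Groups followed the stage and replicate number of the labels, and all libraries were used.

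Genes were tested with edgeR 4.0.16 in R 4.3.3. The default filter of filterByExpr by stage left 18114 genes, and 34194 were not tested. TMM factors, a scaling for composition, lay between 0.8975 and 1.111. A quasi-likelihood model with 1 coefficient per stage was fitted to all 8 libraries, with 4 residual degrees of freedom, 2.698 prior degrees of freedom and a biological coefficient of variation of 0.2501. The 3 differences between stages were tested together, and then each of the 6 pairs of stages, with two-sided F tests and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The SE of a log2 fold change is its size divided by the square root of the F value. CPM were computed with the TMM factors. A prior count of 2 was added for log2 CPM in principal components and list means. Where all libraries of a stage held no count, a fold is a lower bound against 3 counts over the 2 libraries of that stage. Where a stage held 1 to 3 counts, no fold is given. Such floors cover counting error only. Intervals in the closing observations are 95% bootstrap intervals over the genes of a list, from 10000 draws. They measure the spread between genes and leave out variation between libraries.

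Gene lists, 38 in number with 687 genes, were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives, except where stated. The lists cover pathways, uterine and immune cell types, other tissues and technical groups, and 1 of their genes was not in the table. Lists with 4 or more tested members were tested in each pair with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with p adjusted over all lists and pairs. Members past the test over all genes were counted beside those adjusted over the list alone. Camera with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance without comparing them with others, were alternatives.

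Genes to be named were the 10 with the smallest p across the stages. From each consecutive pair came the 8 largest rises and 8 largest falls, and from each opposite pair 4 and 4, among genes past the test with a mean of 5 CPM or more in the higher stage and both libraries of that stage above both of the other. Predicted genes with clone-like or accession-like names were skipped. The rule also took every member of the FAM3 family and of the steroid receptors, and from each other list up to 4 members with the smallest p across the stages and up to 4 in each pair in which the list was called. Some genes that the rule takes are not reported here. Genes outside the rule are marked where they appear as chosen after their values were seen.

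The whole procedure was tested on simulated data with 2 libraries per stage, in which 100 genes changed 4-fold and 100 changed 2-fold in each pair. It recovered 68% to 73% of the former and 8% to 21% of the latter. Of 82 to 104 calls per pair, among 17627 to 17691 genes tested, 1 to 10 were false. The 10 were among 104 calls in the pair of diestrus and metestrus. Only these genes changed in a simulated pair, whereas 92 to 6563 genes were called in the real pairs. The adjusted threshold depends on how many genes change, so these recovered shares need not hold for the real pairs. In the pair of estrus and proestrus, where simulated lists were tested, none of 30 lists without a change was called by camera. The simulated genes varied independently of each other, whereas the mitosis list had an estimated correlation of 0.970 in this pair. The simulation therefore does not test camera on lists of correlated genes.

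Alternatives changed a single choice each: DESeq2 size factors in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter at 1 CPM in 2 libraries, a minimum fold of 2, only the 4 libraries of a pair in the fit, the replicate number as a block, and each library left out in turn. In fits without a library, the genes tested stayed the same and the lone library of its stage was assumed to vary like those of the other stages. A fit without the diestrus stage was added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.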

Results

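Polyadenylated RNA from the uterus of female ICR mice, an outbred laboratory stock, was sequenced at 4 stages of the estrous cycle: proestrus, estrus, metestrus and diestrus. Vaginal smears set the stage, and each stage has 2 libraries, 8 in all. The series title asks how estrogen regulates Fam3d in the uterus over the cycle, so Fam3d and its relatives come first and the other genes follow stage by stage. The deposited counts summed to 21743652 and 21066223 in proestrus, 21391192 and 20102821 in estrus, 21216429 and 21645295 in metestrus, and 21896786 and 17863546 in diestrus, for libraries 1 and 2 of each stage. Of 52308 genes in the deposited table, 18114 had enough counts to be tested. Levels are given as the mean ± SD in CPM, the counts of a gene scaled by the normalised library size, over the 2 libraries of a stage (n = 2), and changes as the log2 fold change ± SE of the edgeR fit to all 8 libraries. Each p-value is adjusted over all genes tested unless stated otherwise. In every one of the 368 calls of a named gene between 2 stages, both libraries of the higher stage lay above both of the lower, which the naming rule itself required of genes taken as the largest rises and falls. The labels leave open whether the libraries of a stage come from separate animals, so the p-values measure only the spread between these samples, which may be technical.

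Proestrus and estrus lay apart from metestrus and diestrus on the first principal component, which held 48.3% of the variance between libraries. The second component held 23.25%. Between the 2 libraries of a stage, 1448 tested genes lay over 2-fold apart in proestrus, 1282 in estrus, 837 in metestrus and 2713 in diestrus. The third component, with 11.4% of the variance, placed diestrus library 1 at 71.5 and diestrus library 2 at -28.1. Prss28 and Prss29, serine proteases of the uterine glands, reached 2039 and 5509 CPM in diestrus library 1 and 0 and 0.0504 CPM in library 2. Ihh, the hedgehog ligand of the uterine epithelium, had 8.46 CPM in library 1 and 92.4 CPM in library 2. The 18 smooth muscle genes summed to 20920 CPM in diestrus library 1 and 8877 CPM in library 2.

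**Figure D1:**
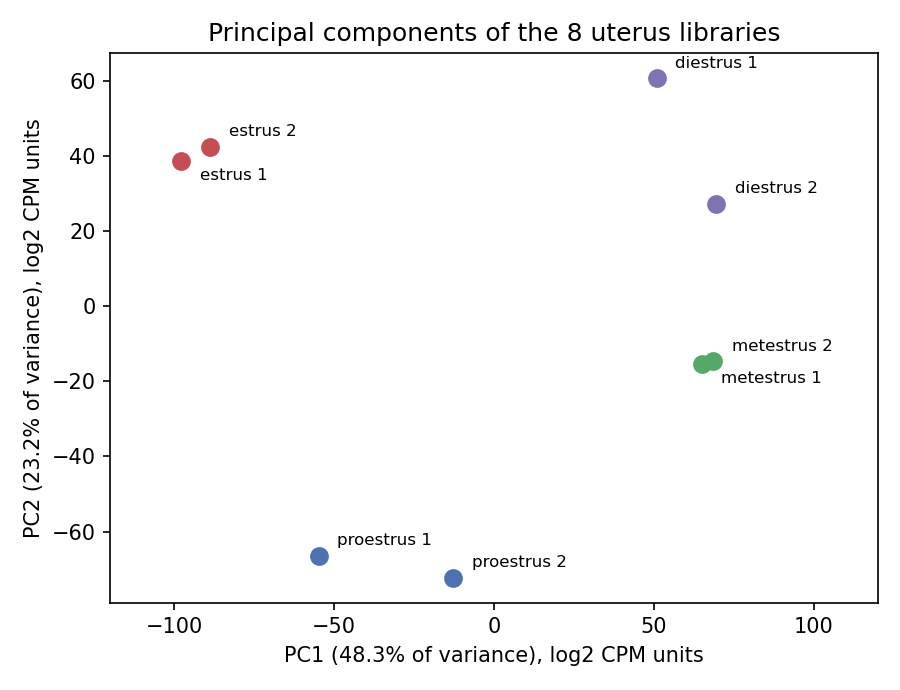
First and second principal components of the log2 CPM of the 18114 tested genes, with the share of the variance on each axis and 1 point per library, coloured by stage. The 4 proestrus and estrus libraries lie at negative values of the first component and the 4 metestrus and diestrus libraries at positive values.

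Fam3d transcripts were high in proestrus and estrus and low in metestrus. Fam3d encodes a secreted protein of the FAM3 family and is annotated as Oit1 (ENSMUSG00000021749, protein coding, minus strand of chromosome 14, from 8348937 to 8378754, GRCm38). Its level was 81.2 ± 9.72 CPM in proestrus, 95.7 ± 0.264 CPM in estrus, 7.75 ± 0.230 CPM in metestrus and 15.2 ± 12.1 CPM in diestrus. The diestrus libraries held 23.8 and 6.71 CPM. Fam3d changed across the 4 stages (adjusted p = 0.00693). It fell from estrus to metestrus by 3.63 ± 0.53 on the log2 scale (adjusted p = 0.00445), a call that held under every alternative run for it. It was higher in proestrus than in diestrus by 2.41 ± 0.50 (adjusted p = 0.0190) and higher in estrus than in diestrus by 2.65 ± 0.51 (adjusted p = 0.0140). It was lower in metestrus than in proestrus, with a log2 fold change of -3.39 ± 0.53 (adjusted p = 0.0105). The changes from proestrus to estrus (0.24 ± 0.47, adjusted p = 0.763) and from metestrus to diestrus (0.98 ± 0.50, adjusted p = 0.347) did not pass the test. Without diestrus library 2 the latter passed (adjusted p = 0.00322). The proestrus-diestrus call ended without proestrus library 1 (0.0890) or 2 (0.0516), the estrus-diestrus call without estrus library 1 (0.0639) or 2 (0.0582), and the metestrus-proestrus call without proestrus library 1 (0.0603) or metestrus library 1 (0.0856) or 2 (0.0942). With only the 4 libraries of the pair in the fit, the first 2 of these calls ended at 0.0942 and 0.0640.

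Of the other members of the family, Fam3b and Fam3c also changed across the stages, and Fam3a did not pass the test. Fam3b (ENSMUSG00000022938, chromosome 16, 97470965 to 97514816), which encodes a secreted protein of pancreatic islets also called PANDER, had 31.8 ± 14.9 CPM in proestrus, 11.7 ± 4.73 in estrus, 0.502 ± 0.0158 in metestrus and 0.121 ± 0.0434 in diestrus (adjusted p = 0.00123 across the stages). Fam3c (ENSMUSG00000029672, chromosome 6, 22306520 to 22356243), the widely expressed ILEI, had 132 ± 12.2 CPM in proestrus, 82.5 ± 4.10 in estrus, 61.8 ± 3.96 in metestrus and 48.3 ± 6.35 in diestrus (adjusted p = 0.00265). Fam3a (ENSMUSG00000031399, chromosome X, 74384719 to 74393272) stood at 52.1 ± 8.44, 44.3 ± 0.303, 32.5 ± 3.33 and 44.2 ± 14.5 CPM in the same order (adjusted p = 0.178), and passed without diestrus library 1 (0.0286) or 2 (0.0234). Fam3b was higher in proestrus than in diestrus by 7.99 ± 0.61 (adjusted p = 0.00124), and Fam3c by 1.45 ± 0.14 (adjusted p = 0.00182). Fam3b fell from estrus to metestrus by 4.53 ± 0.50 (adjusted p = 0.00225). Its change from proestrus to estrus, -1.44 ± 0.40, did not pass (adjusted p = 0.0559; 0.0391 and 0.0427 without diestrus library 1 and 2). Fam3c fell from proestrus to estrus by 0.68 ± 0.13 (adjusted p = 0.0222), a call that ended without any 1 library of proestrus, estrus or metestrus (0.05002 to 0.130). As a list, the 4 genes were higher in proestrus than in diestrus (3 members were higher, also when adjusted over the list alone; adjusted p = 5.42e-05 by camera, a test of the list against the other genes, and adjusted p = 0.268 with an estimated correlation).

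**Figure D2:**
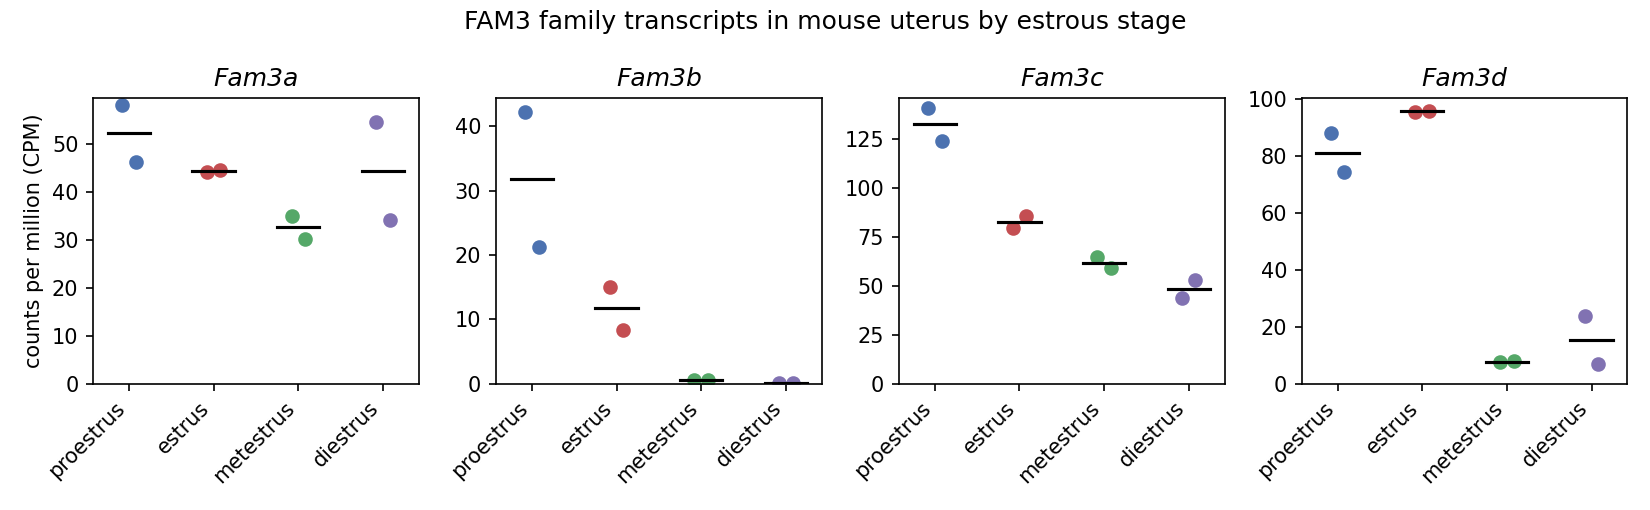
Level of Fam3a, Fam3b, Fam3c and Fam3d in CPM (vertical axis, starting at 0, with a scale of its own for each gene) at each stage (horizontal axis). Points are libraries and horizontal bars the mean of the 2 libraries of a stage, with Fam3d at 95.7 CPM in estrus and 7.75 CPM in metestrus.

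Across the 4 stages, 7085 of the 18114 tested genes changed (39.1%). The 10 genes with the smallest p had adjusted p from 0.000536 to 0.000606 and held under every alternative run for them. Of these, Lrmp, Ass1, Serpinb5, Sfn, B3galt5 and Slc40a1 were high in proestrus and estrus. Ass1, an enzyme of arginine synthesis, had 159, 82.6, 15.1 and 15.2 CPM from proestrus to diestrus. Sfn, an epithelial 14-3-3 protein, had 232, 110, 19.0 and 3.01 CPM over the same stages. Slc40a1, the iron exporter ferroportin, stood at 586 ± 77.5 and 635 ± 4.82 CPM in proestrus and estrus and at 91.2 ± 11.9 and 29.0 ± 3.71 CPM in metestrus and diestrus. Mmp11, a stromal metalloproteinase, had 1260 ± 166 CPM in estrus and between 30.3 and 48.0 CPM in the other stages. Fkbp14, a prolyl isomerase of the endoplasmic reticulum, was lowest in estrus at 5.87 ± 0.454 CPM, against 61.4 to 87.2 CPM elsewhere, and Ppp2r2c was lowest there too (1.20 CPM). Bpifb5, of the family of secreted lipid-binding defence proteins, had 1.94 and 1.85 CPM in proestrus and estrus and 122 ± 17.4 and 87.8 ± 15.7 CPM in metestrus and diestrus. The count of changed genes was 4294 and 4661 without proestrus library 1 and 2, 3086 and 3428 without estrus library 1 and 2, and 3600 and 3452 without metestrus library 1 and 2.

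Of the changed genes, 1687 had their highest mean in proestrus, 2568 in estrus, 1645 in metestrus and 1185 in diestrus. These counts fell to between 820 and 973 for proestrus (every library of proestrus, estrus or metestrus left out in turn, except proestrus library 2 with 1268). For estrus they fell to between 1064 and 1707 (all of these except proestrus library 1 with 1976), for metestrus to between 511 and 1020, and for diestrus to between 532 and 666. Without diestrus library 2, 1907 genes peaked in diestrus. The 38 gene lists, fixed before the data were examined, gave 98 calls among the 6 pairs of stages by camera with a preset correlation of 0.01. None of the 98 held with an estimated correlation (adjusted p from 0.268 to 0.814 in camera of limma, against 4.25e-34 to 0.0447 with the preset), so for each list the members that changed are counted beside the test. These losses do not show that correlation between genes made every call. With an estimated correlation, camera also takes p from the 4 residual degrees of freedom. For the matrix protease list from proestrus to estrus, the estimated correlation of -0.018 lay below the preset. Its unadjusted camera p still went from 1.78e-06 to 0.00637. Lists with a high estimated correlation lost more. For DNA replication from estrus to metestrus it was 0.929, and the unadjusted camera p went from 2.30e-13 to 0.190. For mitosis from proestrus to estrus it was 0.970, and the unadjusted camera p went from 2.75e-12 to 0.215. The small camera p of such lists depends on the preset.

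**Figure D3:**
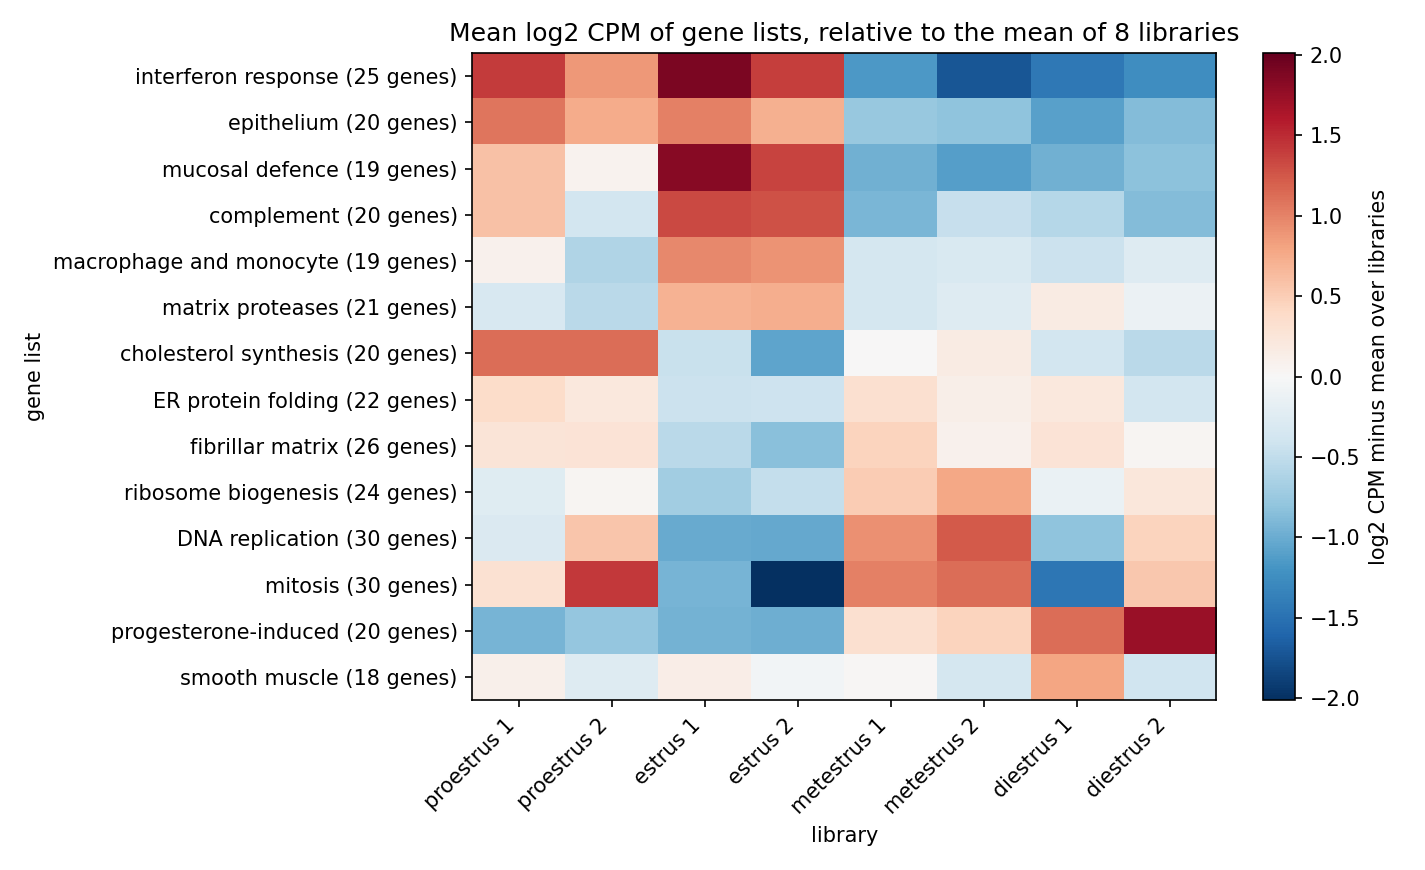
Mean log2 CPM of gene lists (vertical axis, with the number of tested members) in each of the 8 libraries (horizontal axis), relative to the mean over libraries and coloured by the difference. Interferon response genes lie at 0.88 to 1.89 in the proestrus and estrus libraries and at -1.73 to -1.15 in the metestrus and diestrus libraries.

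Among steroid receptor genes, Pgr and Pgrmc1 changed across the stages. Pgr, the progesterone receptor, had 361 ± 34.1 CPM in proestrus, 64.8 ± 5.92 in estrus, 479 ± 1.99 in metestrus and 216 ± 28.9 in diestrus (adjusted p = 0.000854). It fell from proestrus to estrus by 2.48 ± 0.15 (adjusted p = 0.00128) and rose to metestrus by 2.88 ± 0.15 (adjusted p = 0.000739). Pgrmc1, a membrane-associated heme protein, moved the other way at the latter step, from 217 ± 17.9 CPM in estrus to 127 ± 1.45 CPM in metestrus (-0.77 ± 0.11, adjusted p = 0.00379). Its change across the stages (adjusted p = 0.00808) did not pass without estrus library 2 (0.0546). Esr1, the main uterine estrogen receptor, had 450 ± 9.69, 318 ± 24.2, 456 ± 12.1 and 398 ± 88.1 CPM from proestrus to diestrus (adjusted p = 0.109), and passed by DESeq2 (0.0353) and without diestrus library 1 (0.0103) or 2 (0.0142). Gper1 (4.23 to 5.90 CPM; adjusted p = 0.886) passed without diestrus library 2 (0.0238). Esr2 (0.219 to 0.544 CPM), Nr3c1 (53.3 to 64.0 CPM), Nr3c2 (3.02 to 5.38 CPM) and Pgrmc2 (66.5 to 80.4 CPM) did not pass (adjusted p from 0.201 to 0.540).

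The step from proestrus to estrus asks what differs after the preovulatory peak of estrogen, which falls in proestrus. Genes of cholesterol synthesis and of the collagen matrix fell. Of 20 cholesterol genes, 17 fell (19 adjusted over the list alone; adjusted p = 3.25e-23, and adjusted p = 0.268 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, went from 138 ± 1.54 to 35.6 ± 7.004 CPM (-1.96 ± 0.18), and the later enzymes Nsdhl and Lss fell by 1.88 ± 0.17 and 1.81 ± 0.18 (adjusted p from 0.00318 to 0.00404). Of 26 fibrillar matrix genes, 14 fell and 1 rose (15 and 2 adjusted over the list alone; adjusted p = 4.66e-11, and adjusted p = 0.290 with an estimated correlation). The collagen VI chain Col6a3 went from 1990 ± 177 to 193 ± 48.7 CPM (-3.37 ± 0.29), elastin, Eln, from 379 ± 14.8 to 39.4 ± 3.54 CPM and the collagen hydroxylase Plod2 from 247 to 65.9 CPM (adjusted p from 0.00173 to 0.00377). Without proestrus library 1 or 2 or estrus library 1 or 2, the falling matrix genes numbered 8, 7, 9 and 8. Without either diestrus library 3 matrix genes rose, and without any 1 of the other 6 libraries edgeR called none as rising, against 3 by DESeq2, 1 by limma-voom and 3 at an unadjusted p under 0.05 with all libraries. The falling cholesterol genes numbered 9, 8 and 9 without proestrus library 1 or 2 or estrus library 2.

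The falls in single genes from proestrus to estrus reached further. The neurotrophin receptor Ngfr dropped from 626 ± 49.4 to 5.02 ± 2.87 CPM (-6.96 ± 0.49), and Nppc, which encodes C-type natriuretic peptide, from 24.0 ± 3.55 to 0.176 ± 0.176 CPM (-7.03 ± 0.65). The receptor Gpr83, the phosphatase Ptpn5 and the kinase Nrk fell by 6.41 ± 0.64, 6.26 ± 0.46 and 5.92 ± 0.35. Has2, which makes hyaluronan, fell from 7.59 ± 2.03 to 0.127 ± 0.0331 CPM. Igf1, a growth factor that estrogen induces in the uterus, fell from 407 ± 11.02 to 45.9 ± 2.28 CPM (-3.15 ± 0.19). The adjusted p of these genes ran from 0.00128 to 0.00395.

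Genes of macrophages and other immune cells, matrix proteases and Wnt pathway genes were, as lists, higher in estrus than in proestrus. Of 19 macrophage and monocyte genes, 10 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 1.89e-10, and adjusted p = 0.290 with an estimated correlation). Adgre1, the F4/80 marker, went from 30.01 ± 4.47 to 116 ± 6.15 CPM, and Csf1r, the receptor for the macrophage growth factor, from 54.9 ± 19.4 to 250 ± 41.9 CPM (1.95 ± 0.19 and 2.19 ± 0.25; adjusted p = 0.00361 and 0.00545). Of 14 dendritic cell and antigen presentation genes, 10 rose (12 adjusted over the list alone; adjusted p = 3.79e-07, and adjusted p = 0.290 with an estimated correlation), 2 and 1 without proestrus library 1 and 2, 5 and 3 without estrus library 1 and 2, and 6 without either metestrus library. Itgax, the integrin CD11c, rose by 1.92 ± 0.25 (adjusted p = 0.00748). B or plasma cell and T or NK cell genes were called higher as lists too (adjusted p = 0.0121 and 0.01575, and adjusted p = 0.559 and 0.679 with an estimated correlation), though not by fry (0.0795 and 0.110), and the latter not without estrus library 1 (0.0729). With 1 gene called in each, as also when adjusted over the list alone, these were Ighm of 10 (1.71 ± 0.23, adjusted p = 0.00867; 0.0568 without estrus library 1) and Cd4 of 16 (2.14 ± 0.36, adjusted p = 0.01525; 0.0814 without proestrus library 2, 0.0511 and 0.0785 without estrus library 1 and 2). Without either diestrus library, 3 and 4 genes of these lists were called. Where Ighm or Cd4 ended, edgeR called 0 genes of its list, of which 5 and 6 had an unadjusted p under 0.05 with all libraries, and DESeq2 and limma-voom called 1 each. Of 21 matrix proteases and inhibitors, 9 rose and 4 fell (11 and 5 adjusted over the list alone; adjusted p = 9.45e-06, and adjusted p = 0.268 with an estimated correlation). The metalloproteinase genes Mmp11, Mmp9 and Mmp3 rose by 4.71 ± 0.29, 2.94 ± 0.23 and 5.09 ± 0.51, and Adamts5, an aggrecanase, by 1.85 ± 0.20 (adjusted p from 0.00128 to 0.00453). Of 28 Wnt genes, 6 rose and 2 fell (also 6 and 2 adjusted over the list alone; adjusted p = 0.00348, and adjusted p = 0.290 with an estimated correlation). Rspo3, which amplifies Wnt signals, went from 20.6 ± 5.41 to 150 ± 16.5 CPM (adjusted p = 0.00175), and Wnt2 from 0.653 to 6.67 CPM (adjusted p = 0.00553). Among the 8 largest rises were those of Elovl3, a fatty acid elongase (0.202 to 33.5 ± 17.8 CPM, 7.33 ± 0.58), Gpnmb, a lysosomal glycoprotein of macrophages (1.74 to 134 ± 32.5 CPM, 6.26 ± 0.42), Eef1a2 (6.14 ± 0.50) and Trim63, a ubiquitin ligase known from muscle (5.56 ± 0.31), with adjusted p from 0.00128 to 0.00269. Apoc3 and Slco1b2, transcripts of the liver, and Rab3b, a vesicle GTPase, were also among the 8, at 6.07 ± 1.00, 5.64 ± 1.05 and 5.61 ± 0.86 (adjusted p = 0.0257, 0.0339 and 0.0116). Apoc3 and Slco1b2 were not called by DESeq2 (0.388 and 0.433) or without proestrus library 2 (0.0635 and 0.0631), estrus library 1 (0.121 and 0.144) or estrus library 2 (0.0936 and 0.111), nor Slco1b2 without metestrus library 1 (0.0548) or 2 (0.0551). Rab3b was not called without proestrus library 1 (0.0590) or 2 (0.0556) or estrus library 2 (0.0522). Without proestrus library 2 or estrus library 1 or 2, the rising macrophage genes numbered 3, 5 and 4, and the falling gene was past the test in neither limma-voom nor the edgeR fits without proestrus library 1 or any 1 library of estrus or metestrus. Rising Wnt genes numbered 3 without either proestrus library, 2 and 3 without estrus library 1 and 2, and 10 without either diestrus library. As falling, edgeR called 0 Wnt genes without any 1 library of proestrus, estrus or metestrus, 0 proteases without any 1 of proestrus or metestrus and 1 without either of estrus. With all libraries, 2 Wnt genes and 5 proteases had an unadjusted p under 0.05 in that direction, and DESeq2 called 2 and 5 and limma-voom 2 and 4.

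In all, 1470 genes rose and 1257 fell from proestrus to estrus, 2727 together (15.0% of those tested), and 1578 of them by 2-fold or more. Albumin, Alb, a transcript of the liver, had 82.7 and 0.943 CPM in the proestrus libraries and 650 and 477 CPM in the estrus libraries, and at most 0.405 CPM in metestrus and diestrus. The count of changed genes was 779 and 496 without proestrus library 1 and 2, 473 and 459 without estrus library 1 and 2, 1362 without either metestrus library, and 4760 and 4710 without diestrus library 1 and 2. Without the diestrus stage, a fit chosen after the data were seen, it was 4781.

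The step from estrus to metestrus asks what differs once the uterus has passed out of the estrogen-primed phase. Interferon response genes, secreted defence proteins and epithelial genes fell. Of 25 interferon response genes, 23 fell, and 23 when adjusted over the list alone (adjusted p = 9.32e-28, and adjusted p = 0.290 with an estimated correlation). Ifit2, an interferon-induced inhibitor of translation, went from 71.7 ± 6.41 to 6.93 ± 0.549 CPM (-3.37 ± 0.18), the antiviral GTPase gene Mx1 from 24.6 ± 6.78 to 2.62 ± 0.0790 CPM (-3.23 ± 0.26), and Oas2, which activates RNase L, from 137 ± 32.6 to 11.6 ± 3.01 CPM (-3.56 ± 0.33). Tnfsf10, the death ligand TRAIL, fell from 212 ± 1.99 to 40.5 ± 5.48 CPM (adjusted p of these genes from 0.000739 to 0.00163). Of 20 complement genes, 16 fell (17 adjusted over the list alone; adjusted p = 3.66e-09, and adjusted p = 0.290 with an estimated correlation), 10 without metestrus library 2. Of 40 liver markers, chosen after values were seen and from a tissue that also makes complement, 39 fell as well, from sums of 1570 and 1165 CPM in the estrus libraries to 3.79 and 8.34 CPM in the metestrus libraries. The mean log2 level of the complement genes lay above that of the 8 libraries by 0.59 in proestrus library 1 and below it by 0.37 in proestrus library 2, where these markers summed to 450.2 and 46.8 CPM. Complement factor B, Cfb, went from 60.1 ± 0.566 to 0.963 ± 0.0908 CPM, and the regulator Cfi fell by 2.88 ± 0.32. Of 19 mucosal defence genes, 11 fell (13 adjusted over the list alone; adjusted p = 2.65e-06, and adjusted p = 0.268 with an estimated correlation), and 7 without either metestrus library. Lcn2, an iron-trapping protein of uterine fluid, had 10030 ± 1656 CPM in estrus and 81.2 ± 25.6 CPM in metestrus (-6.95 ± 0.53). The surface mucin Muc1 fell by 3.62 ± 0.44, and the glucose transporter Slc5a1 by 4.90 ± 0.32 (adjusted p of Lcn2, Muc1, Slc5a1, Cfb and Cfi from 0.000863 to 0.00294).

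Epithelial, macrophage and protease genes were, as lists, lower after the same step. Of 20 uterine epithelium genes, 15 fell (19 adjusted over the list alone; adjusted p = 2.06e-09, and adjusted p = 0.290 with an estimated correlation). The count was 7, 7 and 6 without estrus library 1 or metestrus library 1 or 2. Prom1, an apical membrane protein, fell by 2.91 ± 0.23, the epithelial transcription factor Elf3 by 2.38 ± 0.21, and the adhesion molecule Epcam from 472 ± 16.8 to 167 ± 3.19 CPM (adjusted p from 0.00114 to 0.00309). Of 19 macrophage genes, 13 fell (15 adjusted over the list alone; adjusted p = 2.30e-06, and adjusted p = 0.485 with an estimated correlation). Adgre1 and Csf1r returned to 37.0 ± 2.38 and 77.3 CPM, and the complement subunit gene C1qb fell from 227 to 87.7 CPM (adjusted p from 0.00248 to 0.00435). Of 21 matrix proteases and inhibitors, 10 fell and 2 rose, as also when adjusted over the list alone (adjusted p = 0.00308, and adjusted p = 0.268 with an estimated correlation). Without either metestrus library 4 fell. The rising genes numbered 4 without diestrus library 1, and 1 without estrus library 2 or either metestrus library. Mmp11 fell by 5.38 ± 0.30 (adjusted p = 0.000806) and Mmp9 by 2.58 ± 0.23 (adjusted p = 0.00151). Immediate early genes, listed as a technical group, were lower as a list too, a call that ended without estrus library 1 (adjusted p = 0.0134 by camera, adjusted p = 0.686 with an estimated correlation and 0.110 by fry). Of 15 such genes, 7 fell (8 adjusted over the list alone). They summed to 1728 and 867.7 CPM in estrus libraries 1 and 2 and to 512.5 and 555.8 CPM in those of metestrus.

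Ribosome biogenesis, DNA replication, protein folding and collagen matrix genes rose from estrus to metestrus. Of 24 ribosome biogenesis genes, 22 rose and all 24 when adjusted over the list alone (adjusted p = 3.67e-15, and adjusted p = 0.446 with an estimated correlation). Polr1a, the large subunit of RNA polymerase I, went from 41.3 ± 1.78 to 98.5 ± 5.87 CPM (1.25 ± 0.13), and Nop2, Nolc1 and Nop16 rose by 1.45 ± 0.16, 1.55 ± 0.19 and 1.17 ± 0.12 (adjusted p from 0.00190 to 0.00282). Of 30 DNA replication genes, 26 rose (28 adjusted over the list alone; adjusted p = 3.50e-12, adjusted p = 0.559 with an estimated correlation and 0.0604 by fry, a rotation test of the list on its own). The S-phase cyclin gene Ccne2, the polymerase gene Pole, the helicase factor Cdc45 and the reductase subunit Rrm2 rose by between 2.68 and 2.88 (adjusted p from 0.00459 to 0.00671). The count of replication genes was 5, 6, 12 and 5 without estrus library 1 or 2 or metestrus library 1 or 2. Of 26 fibrillar matrix genes, 15 rose and 1 fell (18 and 2 adjusted over the list alone; adjusted p = 3.37e-07, and adjusted p = 0.408 with an estimated correlation), and 4 fell without either diestrus library. Serpinh1, the collagen chaperone, went from 453 ± 56.9 to 2200 ± 430 CPM (adjusted p = 0.00128), and Col6a3 returned to 1972 ± 97.7 CPM (adjusted p = 0.00147). Of 22 protein folding genes of the endoplasmic reticulum, 12 rose (13 adjusted over the list alone; adjusted p = 4.39e-05, adjusted p = 0.638 with an estimated correlation and 0.0573 by fry), among them the chaperone Hsp90b1, from 511 ± 89.0 to 1043 ± 18.8 CPM (adjusted p = 0.00410). The folding genes numbered 5, 7 and 7 without estrus library 1 or 2 or metestrus library 1.

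Several single genes rose more steeply from estrus to metestrus. Hsd11b2, which inactivates glucocorticoids, went from 22.2 ± 5.54 to 581 ± 73.3 CPM (4.71 ± 0.29), the noradrenaline transporter gene Slc6a2 from 0.128 ± 0.111 to 32.0 ± 5.89 CPM (7.91 ± 0.73), and Gli1, a transcriptional target of hedgehog signals, from 1.89 ± 1.36 to 149 ± 9.22 CPM (6.29 ± 0.80). Ngfr returned to 447 ± 25.6 CPM and Has2 to 11.4 ± 2.13 CPM (adjusted p of the 5 genes from 0.000821 to 0.00317). In all, 3032 genes rose and 3531 fell, 6563 together (36.2%), 3778 of them by 2-fold or more. Of the transcripts with no count in metestrus, those of the liver were among the largest falls: Apoa1, an apolipoprotein, was at least 939-fold lower than in estrus, and Gc and Bhmt at least 498-fold and 490-fold lower. Apoa1 had 66.6 and 56.3 CPM in the estrus libraries, and the 3 calls ended without estrus library 1 (0.0777 to 0.115) or 2 (0.0589 to 0.105) or metestrus library 1 (0.0765 to 0.122) or 2 (0.0829 to 0.129). The count of changed genes was 2598 and 3364 without estrus library 1 and 2, and 2677 and 2183 without metestrus library 1 and 2.

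From metestrus to diestrus, 51 genes rose and 41 fell, 92 together (0.508%), and 79 by 2-fold or more. At an unadjusted p under 0.05 there were 3318. Zbtb16, a zinc finger factor induced by progesterone and glucocorticoids, rose from 4.51 ± 0.630 to 94.5 ± 53.1 CPM (4.39 ± 0.44), Fst, the activin antagonist follistatin, from 9.21 ± 3.68 to 78.5 ± 7.01 CPM, and the decoy receptor gene Il13ra2 from 1.76 to 20.8 ± 1.17 CPM. Cyp1b1, a cytochrome P450 that hydroxylates estradiol, rose by 5.40 ± 0.70, Hif3a by 4.82 ± 0.56, Adamdec1, a disintegrin-like protease, by 4.79 ± 0.32 and Nt5e, the ectoenzyme that makes adenosine, by 3.24 ± 0.39. Among the falling genes were Gdf6, a ligand of the BMP family (-4.75 ± 0.39), the immunoglobulin segment Ighv8-8 (-5.68 ± 0.42), the nucleotide sugar receptor P2ry14 (159 to 12.6 CPM), Ptpn5 (159 to 16.7 CPM), Nrk (28.4 to 2.53 CPM), the connexin gene Gjb2 (64.5 to 7.12 CPM), Plk2 (224 to 30.6 CPM) and Pgr (-1.15 ± 0.14). The adjusted p of these genes ran from 0.0200 to 0.0398. None of these calls held without metestrus library 1 (0.0909 to 0.338) or 2 (0.119 to 0.375), and except for Adamdec1 none held without proestrus library 1 or 2 (0.0531 to 0.0828). Without estrus library 1 or 2, 11 of the 15 calls ended (0.0549 to 0.102). The count of changed genes was 3 without either proestrus library, 6 without either estrus library, 0 in edgeR without either metestrus library, and 267 and 1985 without diestrus library 1 and 2. It was 992 by DESeq2, 85 by limma-voom, 451 without the filter on low counts, 61 with the replicate number as a block, and 0 in edgeR with only the 4 libraries of the pair in the fit.

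Gene lists moved between metestrus and diestrus with few members past the test. DNA replication genes were lower in diestrus as a list, with a median log2 fold change of -1.13 over 30 genes (adjusted p = 3.00e-14, adjusted p = 0.515 with an estimated correlation and 0.149 by fry). No member was called by edgeR or limma-voom, also when adjusted over the list alone, 5 were by DESeq2, and 16 had an unadjusted p under 0.05. Without diestrus library 2, 22 were called as falling. Ribosome biogenesis genes were lower too (adjusted p = 6.72e-13, adjusted p = 0.485 with an estimated correlation and 0.0897 by fry). No member was called by edgeR or limma-voom over all genes, 9 were by DESeq2, 19 by edgeR when adjusted over the list alone and 20 at an unadjusted p under 0.05. Without diestrus library 2 the count was 11. Of 20 genes that progesterone induces in the uterus, 2 rose (9 rose and 1 fell adjusted over the list alone; adjusted p = 6.01e-09, and adjusted p = 0.268 with an estimated correlation). The rising count was 0 in edgeR without any 1 library of proestrus, estrus or metestrus, against 10 at an unadjusted p under 0.05 and 8 by DESeq2 and 3 by limma-voom with all libraries, and 4 and 8 without diestrus library 1 and 2. Falling members numbered 1 and 4 without diestrus library 1 and 2.

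The pair of proestrus and diestrus asks what changes as the next cycle begins. Interferon response genes, epithelial genes, cholesterol synthesis genes and genes that estrogen induces in the uterus were higher in proestrus. Of 25 interferon response genes, 21 were higher (24 adjusted over the list alone; adjusted p = 1.09e-25, and adjusted p = 0.290 with an estimated correlation). Mx1 had 28.3 ± 0.333 CPM in proestrus and 1.30 ± 0.306 CPM in diestrus (4.45 ± 0.28), Oas2 137 ± 28.7 and 6.87 ± 2.27 CPM (4.33 ± 0.35), and Zbp1, a sensor of Z-form nucleic acids, 96.4 and 2.94 CPM (adjusted p from 0.000918 to 0.00194). Of 20 uterine epithelium genes, 13 were higher (14 adjusted over the list alone; adjusted p = 2.29e-15, and adjusted p = 0.268 with an estimated correlation). Elf3 went from 34.4 ± 0.383 CPM in diestrus to 916 ± 144 CPM in proestrus (4.73 ± 0.24), and the tight junction gene Cldn7 and Epcam were higher by 2.82 ± 0.25 and 2.09 ± 0.19 (adjusted p from 0.000504 to 0.00174). Of 20 cholesterol synthesis genes, 16 were higher (17 adjusted over the list alone; adjusted p = 3.68e-13, and adjusted p = 0.290 with an estimated correlation), 9 without proestrus library 1. Hmgcs1 and Mvd were higher by 1.70 ± 0.18 and 2.61 ± 0.28 (adjusted p = 0.00238 and 0.00264). Of 26 estrogen-induced genes, 16 were higher, and 16 when adjusted over the list alone (adjusted p = 3.50e-12, and adjusted p = 0.268 with an estimated correlation). Without proestrus library 1 they numbered 9, and 10 without proestrus library 2 or either metestrus library. Lcn2 was higher by 8.42 ± 0.57 (adjusted p = 0.000955), and Padi4, which converts arginine in proteins to citrulline, had 119 ± 10.9 and 9.34 ± 3.15 CPM (3.67 ± 0.27, adjusted p = 0.00115).

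Several genes that were higher in proestrus than in diestrus had a wide spread between the proestrus libraries. Sprr2b, a small proline-rich protein of the cornified envelope with close paralogs between which reads are hard to assign, had 551 ± 418 CPM in proestrus and 0.476 ± 0.610 CPM in diestrus (10.21 ± 1.51). Arg1, the arginase of the urea cycle, had 680 ± 576 and 1.501 ± 0.659 CPM (8.83 ± 0.89). Chil1, a chitinase-like protein, had 321 ± 357 and 0.564 CPM (9.17 ± 1.70, adjusted p = 0.0129; 0.131 by limma-voom). The keratin gene Krt6b had 27.9 ± 32.7 CPM in proestrus and 0.0225 CPM in diestrus (adjusted p = 0.0415), a call that ended by limma-voom (0.256), with only the 4 libraries of the pair (0.0615), and without proestrus library 1 (0.124), metestrus library 1 (0.0561) or 2 (0.0560), or diestrus library 1 (0.117) or 2 (0.114). Sprr1a had 124 ± 25.2 and 0.596 CPM (7.65 ± 0.68). Clca1, a secreted regulator of chloride channels and mucus, stood at 2800 ± 1203 and 18.3 ± 14.3 CPM (7.26 ± 0.76), and Padi2 at 1169 ± 670 and 49.1 CPM (4.57 ± 0.44). The adjusted p of Sprr2b, Arg1, Sprr1a, Clca1 and Padi2 ran from 0.00159 to 0.00612. Krt6b and Sprr1a belong to a list of squamous epithelium of vagina and cervix, of which 6 of 14 genes were higher in proestrus than in diestrus (7, with 2 lower, adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.429 with an estimated correlation). The call ended without diestrus library 1 (0.105), where 1 gene was lower, and 3 genes were higher without proestrus library 1. From proestrus to estrus 6 of the 14 fell, as also when adjusted over the list alone (adjusted p = 0.00252, and adjusted p = 0.290 with an estimated correlation), 2 and 1 without proestrus library 1 and 2, 2 and 1 without estrus library 1 and 2, and 3 without either metestrus library. The list summed to 224.6 and 142.2 CPM in the proestrus libraries, 71.4 and 39.1 CPM in those of estrus, and 19.2 to 23.0 CPM in the others.

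Genes that progesterone induces, dendritic cell genes and Wnt pathway genes were, as lists, lower in proestrus than in diestrus. Of 20 progesterone-induced genes, 14 were lower and 1 higher (15 and 1 adjusted over the list alone; adjusted p = 2.06e-09, and adjusted p = 0.268 with an estimated correlation), and 6 were lower without either proestrus library. The homeobox genes Hoxa11 and Hoxa10, which act in implantation, had 184 ± 0.842 and 341 ± 24.3 CPM in diestrus and 49.8 ± 10.3 and 95.8 ± 23.9 CPM in proestrus (adjusted p = 0.00164 and 0.00194). Fst differed by -3.62 ± 0.39 on the log2 scale (adjusted p = 0.00275). Of 28 Wnt genes, 12 were lower and 2 higher (13 and 2 adjusted over the list alone; adjusted p = 0.000598, and adjusted p = 0.268 with an estimated correlation). The antagonists Sfrp1 and Sfrp2 had 67.7 ± 8.72 and 162 ± 39.4 CPM in diestrus and 19.7 and 26.1 CPM in proestrus, while the ligand gene Wnt4 was higher in proestrus, at 46.6 ± 8.74 against 13.4 ± 4.38 CPM (adjusted p from 0.00358 to 0.00512). Without proestrus library 1, 6 Wnt genes were lower, 1 was higher without any 1 library of proestrus, estrus or metestrus, and 4 were higher without diestrus library 2. Of 14 dendritic cell and antigen presentation genes, 10 were lower (11 adjusted over the list alone; adjusted p = 4.32e-06, and adjusted p = 0.290 with an estimated correlation), 5 without either proestrus library. Zbtb46, a transcription factor of classical dendritic cells, had 8.56 ± 1.09 CPM in proestrus and 21.5 ± 1.26 CPM in diestrus (adjusted p = 0.00377). Camera also called endothelial, mast cell and ciliated oviduct genes lower as lists (adjusted p = 0.0115, 0.0354 and 0.0171). Of these, 4 of 15, 4 of 6 and 3 of 7 genes were lower, against 1, 0 and 2 in edgeR with only the 4 libraries of the pair. By fry only the ciliated oviduct list was called (adjusted p = 0.00961, against 0.0690 and 0.170). Each of these camera calls ended without diestrus library 1, and the ciliated oviduct call also without diestrus library 2. The mast cell genes had a mean log2 CPM of 3.385 in diestrus library 1 and 1.514 in library 2. In all, 2175 genes were higher and 1875 lower in proestrus, 4050 together (22.4%), 2462 of them by 2-fold or more. The count was 1246 and 2331 without proestrus library 1 and 2, and 1130 with only the 4 libraries of the pair in the fit.

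Estrus and diestrus, which lie opposite in the cycle, differed in interferon, complement and progesterone-induced genes, with 2511 genes higher and 1806 lower in estrus, 4317 together (23.8%), and 2598 by 2-fold or more. Of 25 interferon response genes, 24 were higher in estrus, and all 25 when adjusted over the list alone (adjusted p = 9.54e-33, and adjusted p = 0.290 with an estimated correlation). Of 20 complement genes, 12 were higher (14 adjusted over the list alone; adjusted p = 2.22e-09, and adjusted p = 0.290 with an estimated correlation), led by Cfi at 3.93 ± 0.34 and Cfb at 6.87 ± 0.66 (adjusted p = 0.00153 and 0.00195). The 40 liver markers were higher in estrus in 35 cases, with sums of 7.87 and 4.19 CPM in the diestrus libraries. Markers of cell types moved in the same pair. Of 20 uterine epithelium genes, 15 were higher in estrus (16 adjusted over the list alone; adjusted p = 9.25e-14, and adjusted p = 0.268 with an estimated correlation), 7 and 9 without estrus library 1 and 2. Of 19 macrophage genes, 13 were higher and 1 lower (15 and 2 adjusted over the list alone; adjusted p = 3.50e-07, and adjusted p = 0.446 with an estimated correlation), and 8 were higher without estrus library 1. Lower macrophage genes numbered 2 without diestrus library 2, and the lower gene was past the test in neither limma-voom nor the edgeR fits without diestrus library 1 or any 1 library of estrus or metestrus. Of 11 fat cell genes, 4 were higher, as also when adjusted over the list alone (adjusted p = 0.0285, and adjusted p = 0.685 with an estimated correlation), a call that ended by fry (0.110) and without diestrus library 2 (0.1125). The higher genes numbered 2 without estrus library 1 or either metestrus library, and 1 was lower without diestrus library 2. The list summed to 731.6 and 539.1 CPM in the estrus libraries, 529.1 and 384.2 CPM in those of proestrus, and 212.1 to 254.1 CPM in the others. Lcn2 and Clca1 were higher in estrus by 9.38 ± 0.59 and 8.50 ± 0.80, and Pigr, which carries IgA across epithelia, had 2743 ± 256 against 156 ± 86.6 CPM (adjusted p from 0.000751 to 0.00295). Of 20 progesterone-induced genes, 13 were lower in estrus and 1 higher (15 and 1 adjusted over the list alone; adjusted p = 2.36e-12, and adjusted p = 0.268 with an estimated correlation). The lower genes numbered 7 and 8 without estrus library 1 and 2. Igf1 had 45.9 ± 2.28 CPM in estrus and 527 ± 119 CPM in diestrus (-3.52 ± 0.19), Hsd11b2 22.2 ± 5.54 and 675 ± 136 CPM (-4.93 ± 0.29), Slc6a2 0.128 and 80.3 ± 22.1 CPM (-9.23 ± 0.73) and Il13ra2 0.278 and 20.8 CPM (-6.19 ± 0.46), with adjusted p from 0.000649 to 0.00129. Apoa1 was at least 863-fold higher in estrus than in diestrus, where it had no count, a call that ended without any 1 library of estrus, metestrus or diestrus (0.0642 to 0.153). The number of changed genes was 1375 and 1741 without estrus library 1 and 2, and 1939 with only the 4 libraries of the pair in the fit.

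Metestrus and proestrus, the other opposite pair, differed in 3067 genes (16.9%), 1210 higher and 1857 lower in metestrus, 1672 of them by 2-fold or more. Of 25 interferon response genes, 23 were lower in metestrus (24 adjusted over the list alone; adjusted p = 4.25e-34, and adjusted p = 0.268 with an estimated correlation), and of 20 uterine epithelium genes 15 (18 adjusted over the list alone; adjusted p = 3.26e-16, and adjusted p = 0.268 with an estimated correlation). Elf3 differed by -2.97 ± 0.22 (adjusted p = 0.00295), a call that held under every alternative run for it. Mx1, Oas2, Oas1a, Epcam and Lcn2 changed by -3.43 ± 0.26, -3.57 ± 0.33, -3.19 ± 0.28, -1.84 ± 0.19 and -5.99 ± 0.51 (adjusted p from 0.00297 to 0.00427), and these 5 calls ended without metestrus library 2 (0.0548 to 0.0571). Of 28 Wnt genes, 10 were higher (15 adjusted over the list alone; adjusted p = 2.06e-05, and adjusted p = 0.268 with an estimated correlation). Without proestrus library 1 or metestrus library 1 or 2, the interferon genes numbered 15, 11 and 0, the epithelial genes 6, 2 and 1, and the Wnt genes 2, 1 and 0, all in edgeR. With all libraries, 24 interferon genes and 17 Wnt genes had an unadjusted p under 0.05, and DESeq2 called 24 and 14 and limma-voom 23 and 9. The Wnt genes also numbered 6 without proestrus library 2, 5 without either estrus library and 17 without either diestrus library. The number of changed genes was 498 and 1667 without proestrus library 1 and 2, 1975 and 1979 without estrus library 1 and 2, 318 and 15 without metestrus library 1 and 2, 5058 and 4983 without diestrus library 1 and 2, and 4769 with only the 4 libraries of the pair in the fit.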

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

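The fit without the diestrus stage was chosen only after the data were seen, and all other alternatives before. Fam3d changed across the stages under the other size factors, DESeq2, limma-voom, both other filter settings and the replicate block, with adjusted p from 3.00e-14 by DESeq2 to 0.00890 with the replicate block, and from 0.00016 to 0.0392 with any 1 library left out. The numbers of changed genes, except that from metestrus to diestrus, stayed within 1.5 times under the other normalization, tests, filters on low counts and block. The replicate numbers did not pair the libraries, since the differences between replicates 1 and 2 of any pair of stages correlated across genes at -0.0926 to 0.145. The labels name no shared animal or batch either, so the fit with the replicate block is not a paired comparison. With 2 libraries per stage, a change of 2-fold was recovered in at most 21% of simulated genes. Fewer genes changed there than were called in the real pairs, except from metestrus to diestrus, so this share need not hold for them. Genes short of the threshold are still not shown to be unchanged. In each case below the cause was not tested. Leaving out a library or using 4 leaves fewer samples, which alone does not account for counts that rose. A minimum fold admits fewer genes.

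With a library left out, the number of changed genes ranged from 3086 to 9479 across the stages, 459 to 4760 from proestrus to estrus, 2183 to 8243 from estrus to metestrus, 0 to 1985 from metestrus to diestrus (edgeR; 3318 genes at an unadjusted p under 0.05 with all libraries), 1246 to 4648 between proestrus and diestrus, 1375 to 5186 between estrus and diestrus and 15 to 5058 between metestrus and proestrus. Genes with their peak in proestrus numbered 820 to 2105, in estrus 1064 to 3016, in metestrus 511 to 2458 and in diestrus 532 to 1907. List calls numbered 91 to 104. Apart from list calls, the lowest values came without a library of estrus or metestrus, except those for proestrus against diestrus and the peak in proestrus, which came without proestrus library 1. The highest came without a diestrus library.

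With only the 4 libraries of a pair, 0 genes changed from metestrus to diestrus by edgeR, where DESeq2 called 992 and limma-voom 85 on all libraries. The same fit gave 1130 between proestrus and diestrus, 1939 between estrus and diestrus and 4769 between metestrus and proestrus. It gave 3449 from proestrus to estrus and 8197 from estrus to metestrus. Counts for pairs with diestrus thus fell against the fit to all libraries, and those for pairs without it rose. The fit to all libraries takes 1 spread per gene over all stages, and the diestrus libraries lay furthest apart. Its p-values may be too small for pairs with diestrus and too large for the others, which was not tested. Without the filter on low counts, 451 genes changed from metestrus to diestrus, and with the replicate block 61. Without the diestrus stage, 4781 genes changed from proestrus to estrus and 5054 between metestrus and proestrus. With a minimum fold of 2, the counts were 4719 across the stages, 1578 from proestrus to estrus, 3778 from estrus to metestrus, 2462 between proestrus and diestrus, 2598 between estrus and diestrus and 1672 between metestrus and proestrus. With an estimated correlation, 0 lists were called by camera, against 77 by fry at the same adjusted threshold and 98 with the preset.

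Of the results for single genes, 43 were no longer past the threshold by limma-voom and 4 by DESeq2, 77 with only the 4 libraries of a pair, 21 with the block, 6 without the filter, 1 with the stricter filter, 2 with the other size factors, and 125 to 177 without a library of proestrus, estrus or metestrus. Without diestrus library 1 or 2, 33 and 76 came to pass it and 18 and 12 ceased to. The sign turned in 1 of these results. Stra6 differed between diestrus and metestrus by 0.48 with all libraries (adjusted p = 0.697), by -0.98 without diestrus library 2 (adjusted p = 0.0238) and by 1.18 without diestrus library 1 (adjusted p = 0.0266). Among list calls, 33 were not past the threshold by fry, 4 with the block and 3 to 15 with a library left out. The smooth muscle list, higher in diestrus than in metestrus (adjusted p = 0.0261), turned its direction without diestrus library 1 (adjusted p = 0.137), and had adjusted p from 2.2e-07 without diestrus library 2 to 0.271 without metestrus library 2.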

Other observations

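Of the tests below, those of the smooth muscle share, the liver transcripts and the clock genes were chosen only after the result was seen. The tests of the stage label and of sequencing depth were written before their values, though after the correlations between libraries had been seen. The genes of retinoid and prostaglandin handling and Tsc22d3, described first, stand in no list and were chosen after their values were seen, and no list of these pathways was tested.

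Single genes known from retinoid handling had their highest means at different stages. Aldh1a2, which makes retinoic acid, had 782 ± 44.5 CPM in proestrus, 86.9 ± 0.822 in estrus, 248 ± 4.01 in metestrus and 165 ± 27.6 in diestrus (adjusted p = 0.000606 across the stages), and Crabp2, which carries retinoic acid to its receptor, was highest in proestrus too (74.2 ± 14.4 CPM against 1.76 to 13.0, adjusted p = 0.00781). Rbp4, the retinol carrier, peaked in estrus at 45.7 ± 0.564 CPM, against 6.44 to 10.4 CPM elsewhere (adjusted p = 0.00247). Both estrus libraries also carried transcripts of the liver, a tissue that makes Rbp4, with Alb at 650 and 477 CPM. The source of the Rbp4 transcripts therefore stays open. Stra6, the receptor for Rbp4, rose from 3.55 ± 0.280 CPM in estrus to 85.4 ± 13.8 CPM in metestrus (adjusted p = 0.00505), and had 43.2 and 195 CPM in the diestrus libraries. Of single genes known from the prostaglandin pathway, Hpgd, the enzyme that inactivates prostaglandins, was highest in estrus at 101 ± 10.6 CPM (adjusted p = 0.00260), and Ptgs2, the inducible cyclooxygenase, had 141 ± 110 CPM in estrus and 7.29 to 17.5 CPM elsewhere (adjusted p = 0.0116; 0.0685 without estrus library 1). The receptor genes Ptger3 and Ptger2 were highest in diestrus, at 103 ± 14.2 and 8.23 CPM (adjusted p = 0.000954 and 0.00206). Zbtb16 and Tsc22d3, both induced by steroid hormones, reached 94.5 ± 53.1 and 168 ± 98.8 CPM in diestrus, against at most 6.01 and 42.3 CPM in the other stages (adjusted p = 0.00141 and 0.01004 across the stages). Except for Ptgs2, these changes across the stages passed under every alternative run for them, where adjusted p reached at most 0.0398.

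The 2 diestrus libraries differed by more than 2-fold at 2713 genes, against at most 1448 between the libraries of another stage. A wrong stage label was predicted to leave a diestrus library at most 1448 genes apart from some library of another stage. The closest such pair, diestrus 2 and metestrus 2, differed at 1855 genes. Diestrus 2 still lay nearer to metestrus 1 and 2 (1945 and 1855 genes) than to diestrus 1 (2713), so the test does not settle its label. For diestrus 1 a wrong label is argued against, since its nearest library of another stage, metestrus 1, differed at 2957 genes. Sequencing depth is argued against as well, since 2768 genes remained after library 1 was thinned to the total of library 2. Smooth muscle genes were higher in library 1 in 18 of 18 cases, with a median log2 ratio of 1.20, so a larger share of muscle may add to the difference, while mitosis and DNA replication genes were higher there in 0 of 30 cases each, with medians of -2.01 and -1.14. A test of this written beforehand, epithelial minus stromal median, did not decide it at -0.36 (-1.13 to 0.33). A later test took the medians of 10 other cell type lists with 10 or more members, which muscle alone would shift alike. The highest and lowest, B or plasma cells (0.98) and neutrophils (-1.50), lay 2.48 apart, a gap reached in 0 of 10000 shuffles of the members over the lists (95th percentile 1.28). The shuffles treat the genes of a list as independent, and immune cells can differ in number between any samples. Neutrophil genes also differed between the estrus libraries, with mean log2 CPM of 2.675 and 1.11. The later test therefore does not decide what part of the difference muscle makes up. No biological explanation was tested, and a difference in time within diestrus, on which the mitosis and replication genes bear, stays open.

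Transcripts of the liver stood out in both estrus libraries and proestrus library 1, where 44 tested markers summed to 2361, 1644 and 1552 CPM, against 321 CPM in proestrus library 2 and 10.2 to 15.1 CPM in the metestrus and diestrus libraries. The marker list was written after several of its genes had been seen, and the 40 of the 44 under 1 CPM in metestrus and diestrus summed, without Uox, to 1448 and 1084 CPM in estrus and to 200.4 and 5.16 CPM in proestrus. Of the 40, 38 (95%) were higher in these 3 libraries than in the other 5, led by Alb at 650 and 477 CPM in estrus, and 39 were called from estrus to metestrus, 35 between estrus and diestrus and 8 from proestrus to estrus, while Arg1 (1087 and 273 CPM) and Uox (249.8 and 41.6 CPM), which made up most of the sums of the proestrus libraries, did not keep the ratio of the others. In proestrus library 1 the 40 were a median 12.1 times those of library 2 (7.90 to 18.5), but library 1 also lay nearer to estrus on the first principal component (-54.9 against -12.7, with -97.9 and -88.8 in estrus). RNA or reads from liver and regulation by the stage cannot be told apart, since both libraries of estrus carry the markers and the 2 proestrus libraries need not stand at the same time of the stage.

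Clock genes differed between estrus and metestrus in opposite directions. In metestrus Nr1d1, Dbp and Per3 were lower, with log2 fold changes of -2.25 ± 0.31, -2.30 ± 0.22 and -1.31 ± 0.15, and Arntl, Clock and Cry1 were higher by 0.82 ± 0.19, 0.89 ± 0.10 and 1.58 ± 0.30 (adjusted p from 0.00181 to 0.0176). A test of collection at different times of day, with arms set after the values were seen, decided nothing, since 3 of the 5 listed members of the Arntl arm moved against the median of the Nr1d1 arm (-1.18), while Npas2 (-1.15, adjusted p = 0.0618) and Nfil3 (-0.19) moved with it, and Ciart of the Nr1d1 arm went the other way (0.57, adjusted p = 0.304). The call of Arntl ended without any 1 library of estrus or metestrus (0.0600 to 0.0969) and that of Cry1 without estrus library 1 (0.0685) or metestrus library 2 (0.0611). Time of collection, which the labels do not give, and regulation by the stage, which was not tested, cannot be told apart.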
